A study of Mus musculus with 20 samples.

How the data were processed

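Gene expression was measured in mouse embryonic fibroblasts, primary connective tissue cells grown from embryos, on 1-colour Affymetrix arrays. There were 20 cultures with 1 array each. Of these, 10 came from 3 wild type embryos (3, 3 and 4 cultures) and 10 from 5 E2F4 null embryos (2 cultures each). The sample titles hold 2 numbers, of which the first was read as the embryo and the second as its culture, from the submitters' design text. Several cultures came from each embryo, so the embryo was the replicate. The labels give no sex, litter, strain, passage or scan batch.

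The deposited values are signal intensities on a linear scale, 1 per probe set and array. They were made with MAS5 per the submitters' processing notes; its version, scaling target and detection calls are not given in the sources used here. The 2% trimmed mean of the deposited intensities was 500.2 on every array, so the arrays had been scaled to a common mean before deposit and were not rescaled. Such scaling sets the average of all probe sets equal and hides a change shared by all genes. Without detection calls, low signals cannot be split into expressed and background, and the filter described next stands in for that. The precision is limited by the number of arrays and embryos.

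The table held 22690 probe sets, of which 64 were controls. In the platform annotation 20393 probe sets had 1 gene symbol, 691 had several and 1555 were unlisted there. Symbols were updated through the gene identifier with the RefSeq gene table of GRCm38.p6, in which 20364 of the 20393 matched. The array files name no genome build, so positions are given as chromosomes of that table. The exceptions are the starts of genes on chromosome 19 and a count of genes within 20 Mb of E2f4 in it. Values were converted to log2(signal + 16), the pseudocount being the 20th percentile of all values, and averaged over the cultures of each embryo. Fold changes are on this scale, which understates the change of low genes. Each gene was represented by the probe set with the highest mean, and genes under the 40th percentile of mean signal were dropped, which left 7436 of 12393 genes.

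Genotypes were compared with limma 3.58.1 in R 4.3.3 on the embryo means (lmFit, eBayes with trend, two-sided, E2F4 null minus wild type), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. There were 29 gene lists, fixed before the data were examined together with the tests, the rule for named genes and most alternatives. The 23 lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, which compares a list with the other genes, adjusted over the lists. Each list was also tested with an estimated correlation, with fry, and by exact permutation of the embryo labels over all 56 splits, whose smallest possible p is 0.0179. Within each genotype, differences between embryos were tested with limma's F test over cultures.

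Named genes were E2f4; up to 12 genes each way with the largest fold change among those called whose embryo groups did not overlap, filled to 5 by the smallest p where fewer qualified and then given as values that did not pass; in each list up to 4 called members or else the 2 with the smallest p; all measured members of the E2F and sex-linked lists; and the 5 genes with the largest F in each genotype. Genes outside this rule are named as chosen after their values were seen.

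The fits were tested on simulated data for 7436 genes, with 200 changed genes and the spreads between embryos and cultures of these arrays. The comparison of genotypes on embryo means recovered 35 of 65 genes changed by 0.5 (log2), 65 of 70 changed by 1 and 65 of 65 changed by 2, and called 8 unchanged genes among 173. With the embryo as a random block it called 66 unchanged genes among 243, above the nominal rate. The F test called 28.7% of the genes simulated with a difference between wild type embryos and 24.3% of those between null embryos, with 25 and 20 false calls. A list moved by 0.3 was called, and so was 1 other of the 23 lists. Genes were simulated independently of each other, while on these arrays cholesterol synthesis genes had an estimated correlation of 0.49. The simulated false calls of genes and lists therefore do not cover genes that move together. With 200 changed genes the adjusted threshold is also looser than where few genes change. The recovered shares may thus be too high for the real comparison, where 1 gene was called and Meox1, at 1.38, was not.

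Alternatives covered the pseudocount (4 and 64), the filter (none, 60th percentile), quantile normalization, median centring, every probe set, cultures with the embryo as a random block or as independent samples, cultures 1 and 2 only, other variance models, embryo or culture number as a block, other list tests, and each embryo left out. After the data were seen, a residual component or Xist as a covariate, the removal of 2 arrays with outlying controls, and the permutation of list means were added. The residual component is the first component of the embryo means once genotype is fitted. By construction it leaves the differences between genotypes unchanged and takes out spread within them. With the embryo number as a block, null embryos 4 and 5 have no wild type embryo of their number. They drop out of that comparison, which rests on embryos 1, 2 and 3 of each genotype. Figures were drawn with matplotlib 3.10.9.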

Results

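The arrays measured mRNA in 20 cultures of mouse embryonic fibroblasts, to compare cells that lack E2F4 with wild type cells. E2F4 is a transcription factor of the E2F family that binds cell cycle gene promoters together with the pocket proteins p107 and p130. All arrays had a trimmed mean signal of 500.2, and median signals ran from 135 to 146. Cultures of 1 embryo correlated across genes at r = 0.988 to 0.994, those of different embryos at 0.950 to 0.991. Each of the 20 cultures was closest to another culture of its own embryo, and no arrays were identical.

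The targeted gene is represented by 1 probe set. E2f4 signal was 214 ± 6.47 (SD, n = 3) in wild type embryos and 166 ± 17.6 (n = 5) in null embryos, and every null embryo lay below every wild type embryo. The difference was -0.35 (log2, SE 0.10), with a limma adjusted p = 0.36, so it did not pass across all genes. The labels do not say which part of the gene was removed, so a probe set outside that part checks nothing.

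Between genotypes, 1 gene fell and none rose at the threshold. Tmem223, which encodes a transmembrane protein, went from 505 ± 43.8 (SD, n = 3) in wild type to 248 ± 26.5 (n = 5) in the null, a change of -0.98 (log2, SE 0.10; limma adjusted p = 0.0347). All 5 null embryos lay below the 3 wild type embryos. The gene has 1 probe set and lies on chromosome 19, as do Otub1, Fads1 and Psat1. The call was lost without wild type embryo 1 or 3 or null embryo 1, 3, 4 or 5 (adjusted p between 0.0599 and 0.187) and held without wild type embryo 2 or null embryo 2 (0.0370 and 0.0466), while the fold change stayed between -1.05 and -0.93. It was also lost with every probe set tested (adjusted p = 0.0531), with cultures 1 and 2 only (0.0601) and with the embryo number as a block (0.213). That block leaves null embryos 4 and 5 out of the comparison. At an unadjusted p under 0.05, limma gave 646 genes, 295 higher and 351 lower in the null, where independent genes would give 372 by chance. Of the 56 splits of the 8 embryos into 3 and 5, the real one included, 9 gave as many, up to 2306. The groups did not overlap for 220 genes above and 276 below wild type, while chance parts the groups fully, in either direction, for 3.57% of genes.

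The genes next in order did not pass. Among those higher in the null, Meox1, a homeobox transcription factor of somites, had 57.4 ± 18.7 (SD, n = 3) in wild type and 169 ± 23.4 (n = 5) in the null, a log2 difference of 1.38 (SE 0.19, limma adjusted p = 0.109). Fads1, a fatty acid desaturase, differed by 0.38, Psat1, an enzyme of serine synthesis, by 0.32, the chloride transporter Clcn3 by 0.54 and Mvb12b, a subunit of the ESCRT-I sorting complex, by 0.37 (adjusted p = 0.192 to 0.195). The other probe sets of Mvb12b differed by 0.05 and 0.08 only, and those of Clcn3 by 0.17 to 0.39. Among those lower, Otub1, a deubiquitinase, differed by -0.71 (adjusted p = 0.109), and its other probe set by -0.47. Mgst3, a microsomal glutathione transferase, differed by -0.54, the lysyl hydroxylase Plod3 by -0.39 and the NF-kappaB inhibitor Nfkbia by -0.57 (adjusted p = 0.192), with its other probe sets at -0.61 to -0.21. For each of these 9 genes the 5 null embryos lay on 1 side of the wild type embryos. Without wild type embryo 2 Meox1 and Plod3 passed (adjusted p = 0.0370 each), and with the embryo as a random block over cultures, a setting that called too many genes in simulated data, 7 of the 9 did, all but Clcn3 and Mvb12b. With the residual component as a covariate, which was added after the data were seen, all 9 passed. That covariate leaves the differences unchanged and takes out spread within genotypes, which favours smaller p. With it, 11 of the 56 splits gave as many called genes as the real one.

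**Figure D1:**
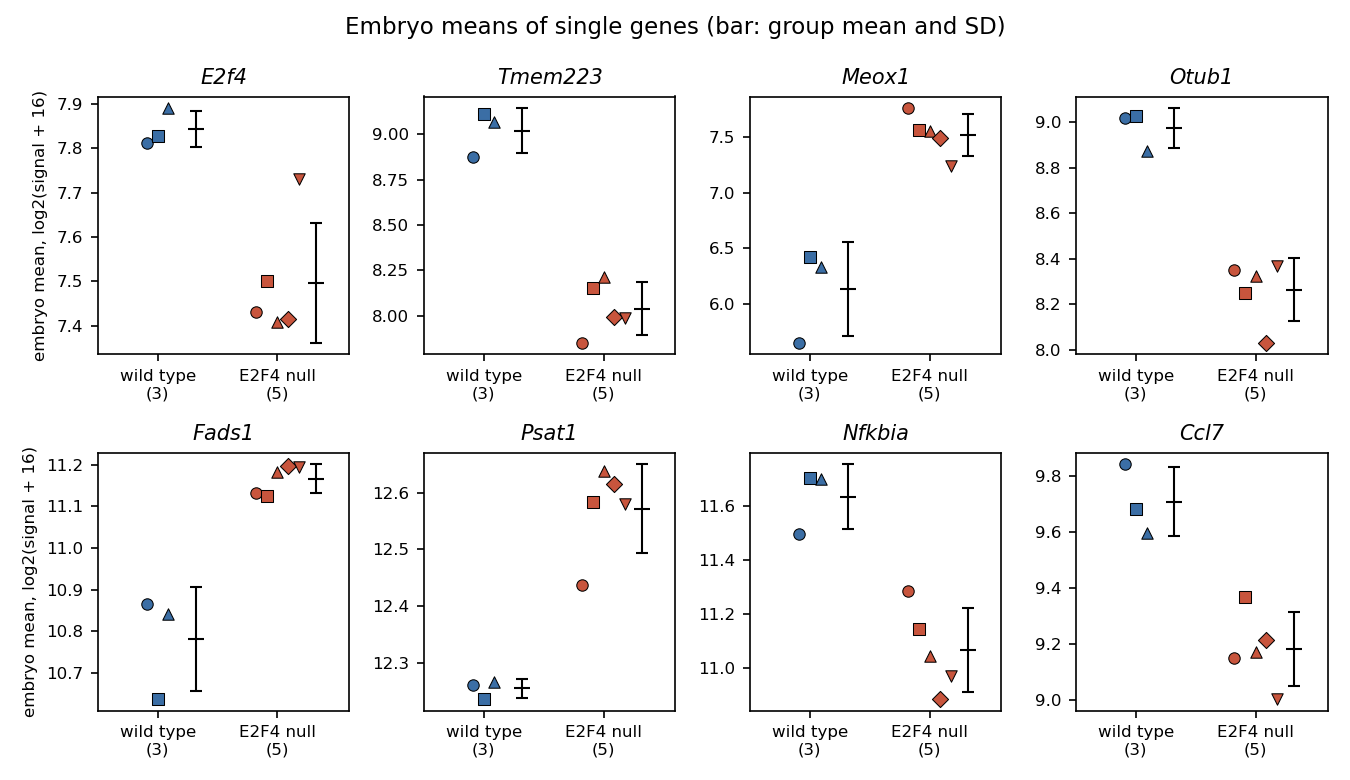
Embryo means of 8 genes as log2(signal + 16), with 3 wild type embryos in blue and 5 E2F4 null embryos in red, and a bar for the group mean and SD. The groups do not overlap for any of the 8, and E2f4 of null embryo 5, at 7.73, lies closest to the wild type embryos.

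Genes of cholesterol synthesis were higher in the null as a group. Of 19 measured, 17 lay above 0, with a median difference of 0.33 (log2), and the list passed camera with an adjusted p = 8.3e-12. With an estimated correlation, which was 0.49 among its genes, the adjusted p was 0.311, and with fry it was 0.121. The exact permutation gave p = 0.0357 (0.274 adjusted over the lists). No single gene passed across all genes, and 12 were higher when adjusted over the list alone. The sterol dehydrogenase Nsdhl had 1358 ± 159 (SD, n = 3) in wild type and 1870 ± 136 (n = 5) in the null, and lanosterol synthase, Lss, 571 ± 21.0 and 864 ± 139, differences of 0.46 and 0.57. The 5 null embryo means of the list lay above the 3 wild type means.

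Glycolysis and hypoxia genes were also higher, with 18 of 20 above 0, a median of 0.17 and a camera adjusted p = 9.4e-06 (adjusted p = 0.311 with an estimated correlation). None passed when adjusted over the list alone. The glycolytic enzyme Tpi1 differed by 0.19 and the glucose transporter Slc2a1 by 0.23. The list mean of wild type embryo 2 deviated by 0.11, above 4 of the 5 null embryos, and without that embryo the mean difference went from 0.21 to 0.32 (adjusted p = 4.9e-11). The list of endoplasmic reticulum and amino acid stress genes was higher with a median of 0.16 over 30 genes (adjusted p = 9.8e-05, and adjusted p = 0.311 with an estimated correlation), of which 6 were higher and 1 lower when adjusted over the list alone. Its smallest p belonged to enzymes of serine synthesis rather than of protein folding, Psat1 at 0.32 and Phgdh at 0.24. The call of this list was lost without wild type embryo 3 (mean difference 0.04 against 0.11, adjusted p = 0.0795).

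Secreted inflammatory genes were lower in the null. Of 16 measured, 15 lay below 0, with a median of -0.36 and a camera adjusted p = 0.00022 (adjusted p = 0.140 with an estimated correlation, 0.0401 with fry). When adjusted over the list alone, 2 fell. These were Nfkbia and the chemokine Ccl7, which had 824 ± 71.0 (SD, n = 3) in wild type and 569 ± 53.1 (n = 5) in the null. Nfkbia is not secreted but holds NF-kappaB in the cytoplasm and is itself one of its target genes. The list mean of wild type embryo 2 deviated by -0.16 and lay among the null embryos, at -0.24 to -0.02. Without that embryo the mean difference went from -0.37 to -0.56 (adjusted p = 6.0e-05), and without wild type embryo 1 to -0.24 (adjusted p = 0.00670). Immediate early and serum response genes were lower too, 17 of 21 below 0, with a median of -0.23 and an adjusted p = 0.00097 (adjusted p = 0.311 with an estimated correlation). Zfp36, which destabilises cytokine mRNAs, differed by -0.59 and the nuclear receptor Nr4a1 by -0.64, and none of the list passed when adjusted over the list alone. Without wild type embryo 1 the mean difference went from -0.27 to -0.17 (adjusted p = 0.0370). HOX genes lay below 0 in 12 of 13, with a median of -0.23 and an adjusted p = 0.0163 (adjusted p = 0.311 with an estimated correlation). Hoxc8 differed by -0.43 and Hoxa10 by -0.39. This call was lost without wild type embryo 1 (mean -0.15 against -0.21, adjusted p = 0.111) and with no filter on low genes (mean -0.10, adjusted p = 0.0959). Collagen and matrix genes had a median of -0.10 over 42 genes and an adjusted p = 0.0241 (adjusted p = 0.665 with an estimated correlation), with the protease inhibitor Timp1 at -0.49 and Col18a1 at -0.53. This call was lost without wild type embryo 1, where the mean went from -0.12 to -0.04 (adjusted p = 0.288), and, with means that stayed about as large, without null embryo 4 (-0.11, adjusted p = 0.0601) or null embryo 5 (-0.10, 0.133) and with cultures 1 and 2 only (-0.10, 0.0599).

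Cell cycle genes, the class to which E2F4 binds, gave no call that kept its direction without wild type embryo 2. G2/M and mitosis genes lay above 0 in 51 of 53, with a median of 0.14 and a camera adjusted p = 6.5e-05 (adjusted p = 0.764 with an estimated correlation). Kif22, a mitotic kinesin, differed by 0.36 and Anln, a protein of cytokinesis, by 0.21. The list mean deviated by -0.48 in wild type embryo 2 and lay between -0.13 and 0.21 in the other embryos. Without that embryo the mean difference turned from 0.15 to -0.04 (adjusted p = 0.305), and without wild type embryo 3 it was 0.30 (adjusted p = 1.4e-13). G1/S and DNA replication genes lay above 0 in 32 of 46 and did not pass (mean 0.08, adjusted p = 0.106), with Rfc4 at 0.35 and Pold3 at 0.34. The list passed as lower without wild type embryo 2 (mean -0.14, adjusted p = 0.000202) and as higher without wild type embryo 3 (0.24, adjusted p = 1.6e-07), wild type embryo 1 (0.12, 0.0454), null embryo 1 (0.13, 0.0126) or null embryo 2 (0.12, 0.0303). On all 8 embryos it also passed as higher with 2 covariates added after the data were seen, Xist (0.11, adjusted p = 0.0166) and the residual component (adjusted p = 0.00229). All of these used camera's preset correlation of 0.01. The estimated correlation among G1/S genes was 0.82, and with it the adjusted p on all embryos was 0.824. The list of E2F, pocket protein and DREAM complex genes had an adjusted p = 0.809, with 5 of 13 above 0. By the probe sets used, its largest differences were Lin9 at 0.24 and Rb1 at -0.21, followed by Rbl1 at -0.12, E2f5 at 0.12, E2f6 at -0.11, Lin37 at -0.10, Rbl2 at -0.09 and Mybl2 at 0.09. E2f1, E2f3, E2f8, Tfdp1 and Rbbp4 lay between -0.04 and 0.01. Other probe sets gave -0.28 for Rbl2, -0.14 for E2f1, -0.05 for E2f5, -0.13 for Rbl1, 0.08 for Mybl2, and -0.02 and 0.12 for Rbbp4. Cyclin-dependent kinase inhibitor and D cyclin genes were split 6 and 6 (adjusted p = 0.819), with Cdkn1b at -0.25 and Cdkn2d at 0.11. DNA repair genes (adjusted p = 0.0715, Blm at 0.32, Exo1 at 0.30) and p53 target genes (adjusted p = 0.424, Btg2 at -0.86, Sesn2 at 0.34 and 0.05 by its other probe set) did not pass. DNA repair genes passed as higher without wild type embryo 3 (mean 0.18 against 0.09, adjusted p = 0.00277) or null embryo 1 (0.12, adjusted p = 0.0185), and on all embryos with Xist (0.10, adjusted p = 0.0368) or the residual component (adjusted p = 0.0101) as a covariate. These too used the preset correlation. The estimated one was 0.27, with a camera adjusted p = 0.764 on all embryos.

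**Figure D2:**
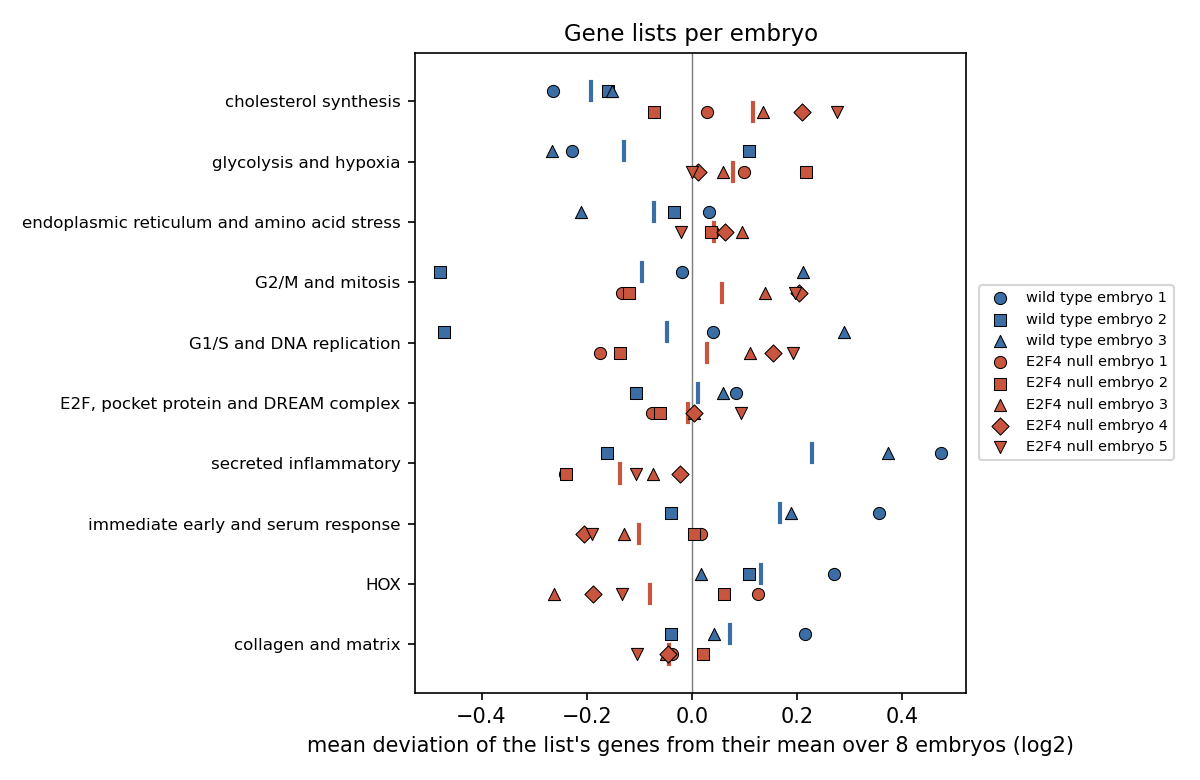
Mean deviation of each list's genes from their mean over the 8 embryos (log2), 1 symbol per embryo, wild type in blue and E2F4 null in red, with a bar for the group mean. For cholesterol synthesis the 3 wild type embryos lie between -0.27 and -0.15 and the 5 null embryos between -0.07 and 0.28; the G2/M list of wild type embryo 2 lies at -0.48.

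Smaller calls lay nearer the threshold or depended on the settings. Ribosomal protein genes had a median of 0.05 over 30 genes (adjusted p = 0.00595, and adjusted p = 0.764 with an estimated correlation). With quantile normalization their mean was 0.01 (adjusted p = 0.662), and the call was also lost without wild type embryo 1 or 3 (means 0.01 and 0.03 against 0.05) or null embryo 2 (0.02), while without wild type embryo 2 the mean was 0.10 (adjusted p = 3.8e-06). Rpl14 differed by 0.19 and Rpl7 by 0.10. Adipocyte genes (median 0.14) and macrophage and leukocyte genes (median 0.24) each had an adjusted p = 0.0428 (adjusted p = 0.311 and 0.773 with an estimated correlation), with means of 0.13 and 0.22. Neither passed with quantile normalization (means 0.14 and 0.22, adjusted p = 0.0569 and 0.0722) or median centring (0.15 and 0.23, adjusted p = 0.0632 and 0.0667), where the means stayed about as large. The macrophage list of null embryo 4 deviated by 0.75 and that of null embryo 1 by -0.48, and the mean difference went from 0.22 to 0.05 without null embryo 4 (adjusted p = 0.567), 0.06 without wild type embryo 3 (0.753), 0.14 without wild type embryo 1 (0.288), 0.36 without null embryo 1 (0.000748) and 0.44 without wild type embryo 2 (0.000308). The list also lost its call without null embryo 2 or 5 (adjusted p = 0.0906 and 0.05002), where the mean stayed about as large (0.21 each). The adipocyte call was lost without any 1 of the wild type embryos or null embryo 3, 4 or 5, where the mean ran from 0.08 to 0.19 against 0.13 (adjusted p = 0.0541 to 0.123). The embryo number as a block leaves null embryos 4 and 5 out of the comparison. With it, the adipocyte and macrophage means fell to 0.03 and 0.01 (camera adjusted p = 0.354 and 0.644). With no filter they were 0.07 and 0.16 (0.248 and 0.106). Over all alternatives, 18 of 29 ended the adipocyte call and 17 of 28 the macrophage call. The fatty acid enzymes Scd1, at 0.44, and Fasn, at 0.18, headed the first, and Laptm5, at 0.35, and Cd14, at 0.32, the second. Scd1 was higher when adjusted over the list alone. Without the 2 arrays with outlying controls, an alternative chosen after the data were seen, none of these 3 lists passed (adjusted p = 0.161, 0.0684 and 0.0545). The ribosomal mean was then 0.02 against 0.05, while the adipocyte and macrophage means stayed at 0.13 and 0.22.

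The other lists did not pass. Their adjusted p was 0.0650 for imprinted genes (Slc38a4 at 0.34, Nnat at 0.43), 0.0963 for smooth muscle and contractile genes (Ccn1 at -0.53, Vcl at -0.24), 0.321 for interferon response genes (Irf9 at 0.24, Irf1 at 0.16) and 0.321 for fibroblast and mesenchymal marker genes (Prrx2 at -0.47, Zeb1 at -0.19). It was 0.803 for cilium genes (Ift20 at -0.23, Arl3 at -0.17), 0.819 for neural and glial genes (Gap43 at 0.31, Ncam1 at -0.13) and 0.908 for oxidative phosphorylation genes (Ndufa4 at -0.24, Atp5j at -0.13). Smooth muscle genes, with a mean of -0.13, passed as lower without wild type embryo 3 (-0.30, adjusted p = 0.00403), null embryo 2 (-0.24, 0.00104) or null embryo 1 (-0.19, 0.0188) and with quantile normalization (-0.15, 0.00919), and lay at 0.09 without wild type embryo 2. On all embryos they also passed with the embryo as a random block (-0.12, adjusted p = 0.0471), with Xist (-0.17, 0.0233) and with the residual component (0.0101) as a covariate. Interferon response genes passed as higher without wild type embryo 2 (mean 0.17 against 0.05, adjusted p = 0.0429), and imprinted genes without wild type embryo 2 or null embryo 2 (adjusted p = 0.0429 and 0.0461). On all embryos imprinted genes passed as higher in 5 alternatives, which were the embryo as a random block (adjusted p = 0.0240), independent cultures (0.0454), the culture number as a block (0.0301) and the residual component (0.0264) or Xist (0.0368) as a covariate. All these passes used the preset correlation, while the estimated one was 0.80 among smooth muscle genes. With estimated correlations, camera's adjusted p on all embryos was 0.824 for smooth muscle, 0.824 for interferon response and 0.311 for imprinted genes. Too few members were measured to test skeletal muscle (3), cartilage and bone (4), endothelial (2), epithelial (2), erythroid (0) and sex-linked (1) genes. Of these, Acta1 differed by -0.78, Tnnt2 by 0.30, Col2a1 by 0.33, Acan by -0.42, Eng by 0.24, Flt1 by -0.28, Krt19 by 0.51 and Krt18 by 0.38.

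Of the 23 lists, 7 were higher and 4 lower with the preset correlation. With an estimated correlation 0 passed, with fry 1, the secreted inflammatory genes, and by exact permutation 0. The permutation result says little, since with a smallest p of 0.0179 no list could pass alone after adjustment over 23. With the embryo number as a block, the G2/M, HOX and collagen lists were among those lost (adjusted p = 0.0592, 0.0509 and 0.345). Their means were 0.06, -0.16 and -0.09 against 0.15, -0.21 and -0.12. That setting compares embryos 1, 2 and 3 of each genotype only. The labels do not say whether the embryo number pairs the samples. Array controls also differed between genotypes. The Gapdh 3'/5' ratio was 0.741 ± 0.00601 (SD, n = 3) in wild type embryos and 0.712 ± 0.00748 (n = 5) in null embryos, with no overlap (exact permutation p = 0.0179, adjusted p = 0.0537 over 6 measures). The 18S rRNA control was 829.8 ± 713 and 108 ± 18.2, likewise without overlap (exact permutation p = 0.0179). Much of that wild type mean came from 1 culture, culture 1 of wild type embryo 2 at 4572. Without it the wild type control was 342 ± 165 (SD, n = 3), with its lowest embryo at 184 and the highest null embryo at 128. Single arrays did overlap. The Gapdh ratio was 0.716 in culture 3 of wild type embryo 1 and 0.749 in culture 2 of null embryo 5. The 18S control was 96.1 in culture 4 of wild type embryo 3 and 168 in culture 2 of null embryo 1. The Actb 3'/5' ratio was 1.15 ± 0.0131 and 1.14 ± 0.0368 (exact permutation p = 0.929). A 2-sided permutation test of 3 against 5 embryos cannot go below 0.0179.

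Embryos of 1 genotype differed from each other in many genes. By limma's F test over cultures, 3722 genes (50.1%) differed between the 3 wild type embryos and 1703 (22.9%) between the 5 null embryos, and 1415 genes did so in both, where independent lists would share 852. Genes with a small error enter both lists more easily, which that number leaves out. Wild type embryos had 3 or 4 cultures and null embryos 2, so the 2 tests differ in power and their counts are not comparable. With cultures 1 and 2 only, the wild type count was 2172. The counts depended on single embryos: without wild type embryo 2 the first was 1119, and without null embryo 2 the second was 983. The median SD between embryo means was 0.15 in wild type and 0.13 in the null, against 0.12 and 0.11 between cultures of 1 embryo.

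Xist, the RNA of the inactive X chromosome, had the largest F in wild type (2515; limma adjusted p = 4.1e-15). Its signal was 2218 to 3070 in wild type embryos 1 and 3 and null embryos 1, 4 and 5, and 30.5 to 47.1 in wild type embryo 2 and null embryos 2 and 3. The Y-linked Eif2s3y, below the filter as a gene and chosen after its values were seen, read 350 to 679 in the latter 3 and 0.44 to 5.01 in the former 5. Lum, a matrix proteoglycan, ranged from 6.61 (log2) in wild type embryo 2 to 11.13 in wild type embryo 3, and Gjb2, a gap junction protein, from 8.14 to 10.78. Rpgrip1 was at 6.78 in wild type embryo 1, 9.98 and 10.27 in wild type embryos 2 and 3 and at 10.65 or above in the null embryos. Its other probe sets did not show this. They were dim, at 4.12 to 5.35, under the lowest mean of the tested genes (6.59), and differed between genotypes by 0.11 to 0.29 against 2.11.

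Among null embryos, Nol11, a factor of ribosome assembly, had the largest F (747; limma adjusted p = 5.0e-11). It was at 4.99 in null embryo 3 and 5.05 in wild type embryo 3, and between 9.57 and 9.91 in the other 6, although 1 of its 3 probe sets did not show this. The actin-binding Cap1 was at 8.57 in null embryo 2 and 9.68 in wild type embryo 2, and at 11.08 to 11.87 elsewhere. Plac8 was between 10.56 and 11.52 in null embryos 1 and 2 and wild type embryo 2 and between 8.06 and 8.73 in the other 5. The proteoglycan Sdc4 was at 8.76 to 9.03 in those 3 embryos and at 11.55 or above elsewhere, and its other, dimmer probe set did not part the embryos in this way.

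Of the lists, most cell cycle genes differed between embryos: 44 of 46 G1/S genes and 49 of 53 G2/M genes in wild type, 30 and 34 in the null. Collagen and matrix genes did so in 39 and 31 of 42, and secreted inflammatory genes in 12 and 14 of 16. Of 41 oxidative phosphorylation genes 16 and 4 differed, and of 30 ribosomal protein genes 14 and 2. Cholesterol synthesis genes differed in 12 and 12 of 19. Over all genes tested, 50.1% differed between wild type and 22.9% between null embryos.

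**Figure D3:**
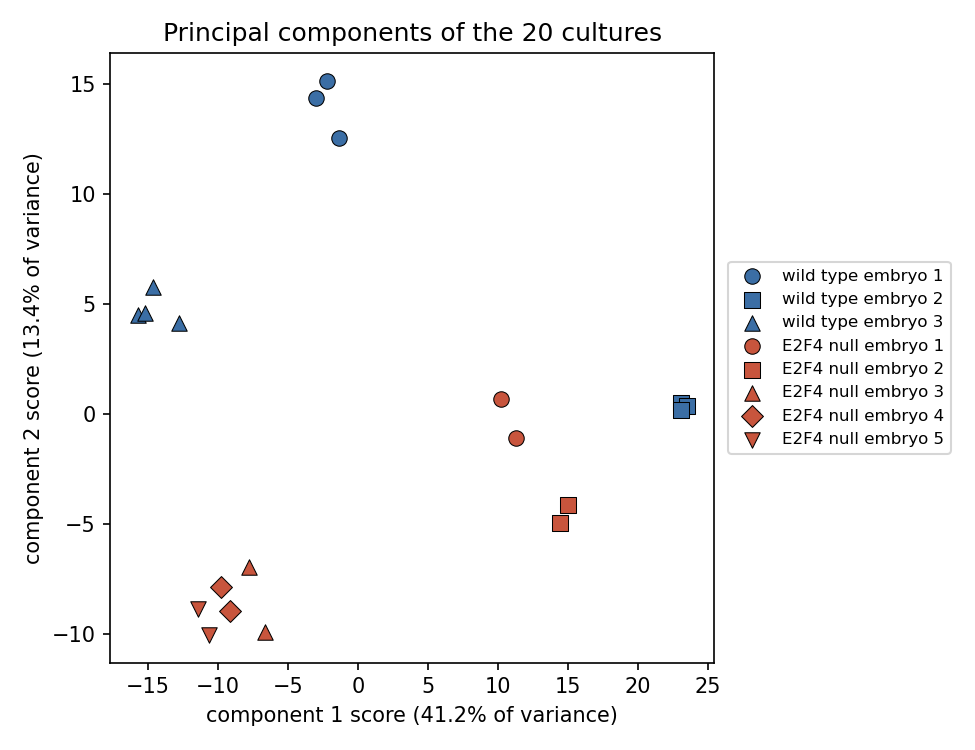
Scores of the 20 cultures on the first and second principal components of log2(signal + 16), 1 symbol per embryo, wild type in blue and E2F4 null in red. Cultures of 1 embryo lie together, and component 1, with 41.2% of the variance, does not part the genotypes: wild type embryo 2 lies at one end and wild type embryo 3 at the other. Component 2, with 13.4%, runs from 0.18 to 15.2 in wild type cultures and from -10.0 to 0.68 in null cultures.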

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

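The tests on the number of genes and lists called, on sex and on second probe sets were chosen after the results were seen. Those on array brightness (98th percentile of scaled signal), RNA ratios, proliferation, the random block count and the split of wild type cultures were written before. So was the test of chance clustering on a chromosome, but the chromosome and the number of genes were chosen after their values were seen. Of 105 results tested for a null embryo far from the others, 12 were, among them 2 of the 5 genes named for their differences between null embryos. Without those 5 genes 10 of 100 were, where chance gives about 5.

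Chromosome 19 held 9 of the 50 genes with the smallest p between genotypes, where 1.75 would be its share (one-sided Fisher's exact p = 4.8e-05, adjusted p = 0.00107 over chromosomes). They were Tmem223, Otub1, Bscl2, Yif1a and the noncoding Malat1, lower in the null, and Fads1, Psat1, Scd1 and Scd2, higher; Malat1, Yif1a, Bscl2 and Scd2 were chosen after their values were seen. The chromosome and the number of 50 genes were also chosen then. Only the real split, 1 of 56, gave any chromosome so small a p, though another came close, with 6.1e-05 for chromosome 8 when wild type embryo 3 and null embryos 1 and 2 were set against the rest. Of the 9 genes, 7 had a second probe set that went the same way by over 2 standard errors, which argues against a fault of single probe sets for these (of 12 second probe sets 11 did so, and 1 of Yif1a did not); 2, Tmem223 and Fads1, had none, so a fault cannot be told apart from a change in mRNA there. E2f4 lies on chromosome 8, where 1 of 168 tested genes within 20 Mb of it was among the 50. In the gene table the 9 genes start between 5088538 (Yif1a) and 15905123 (Psat1), apart from Scd2 and Scd1 at 44293676 and 44394450. Psat1 and Scd1 also belong to lists called higher in the null. A chromosome 19 segment of another strain that the null embryos share may be a source for some or all of the 9. To hold all of them, 1 segment would have to reach from Yif1a to Scd1. The labels give no strain, and this was not tested.

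The first component of the embryo means, with 50.5% of the variance, ran from 22.3 in wild type embryo 2 to -13.9 in wild type embryo 3, with null embryos 2 and 1 at 14.6 and 10.7 and the others between -12.5 and -1.55. Array brightness, as the 98th percentile of the scaled signals, gave 3.28% of that range by its slope among cultures of 1 embryo (95% interval -2.84 to 9.39). The Actb 3'/5' ratio gave -1.94% (-6.08 to 2.20). The arrays were scaled before deposit, so a difference in raw brightness could not be tested. Sex alone is argued against by null embryo 3, at -8.52 without Xist signal, below null embryo 1, at 10.7 with it. Acta1, Pmaip1, Plac8, Tgm2 and Cnn1 weighed on the positive side and Cxcl5, Lum, Gas1, Sfrp2 and Pdgfra on the negative; apart from Acta1, Plac8 and Lum they were chosen after their values were seen. Genotype does not part the embryos on it, and litter, passage and growth state, none of them in the labels, stay open as an untested biological or culture difference. On the second component, with 16.4% of the variance, wild type embryos lay at -15.7, 0.60 and -7.47 and null embryos between -1.09 and 6.64. Only null embryo 1, at -1.09, lay below wild type embryo 2 there.

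The higher level of cholesterol synthesis genes in the null was a log2 mean of 0.31 (SE 0.09) and 0.27 (SE 0.09) with the G2/M list mean as a covariate, which argues against proliferation as the whole cause. The 98th percentile of the scaled signals gave -6.50% of the difference by its slope within embryos (95% interval -12.5 to -0.54) and the Gapdh 3'/5' ratio -0.64% (-8.24 to 6.95). That percentile does not measure raw brightness, which the scaling removed. The list difference stayed at 0.31 with quantile normalization and 0.32 with median centring. A change in sterol synthesis with E2F4 loss is one hypothesis that these values leave open. So are differences in medium, density or batch that go with genotype, since the embryo means of the Gapdh ratio and the 18S control part the genotypes fully. Single arrays of both measures overlap between genotypes.

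E2f4 of null embryo 5 was at 7.73 (log2), with the other null embryos at 7.41 to 7.50. Null embryo 1 stood apart for Psat1 (12.44), Mvb12b (9.67), Ncam1 (10.19), Tpi1 (12.47) and Prrx2 (9.43). Null embryo 2 did so for Gap43 (7.34), Rbbp4 (12.13) and Cap1 (8.57), null embryo 3 for Nol11 (4.99) and null embryo 5 for Lin37 (7.58). The oxidative phosphorylation list of null embryo 4 was at 0.025, with the others at -0.013 to -0.0024.

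The comparisons left out the probe sets with several genes or none listed. Of these, 984 reached the lowest mean of the tested genes, and 2 passed between genotypes (limma adjusted p = 0.0195). The one with no gene listed was lower in the null by -0.58 (log2), and the other, with 2 genes listed, was higher by 0.60.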

How the results depend on the processing

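The residual component, Xist, the removal of 2 arrays and the permutation of lists were added after the data were seen. The fold change of Tmem223 stayed between -1.05 and -0.86 over all 25 alternatives, and 9 of them ended its call. Genes lower numbered 0 with every probe set, with cultures 1 and 2 only and with the embryo number as a block, against 1. With the embryo as a random block 27 genes were higher and 53 lower, with independent cultures 241 and 303, where E2f4 also passed (-0.35), with the culture number as a block and the embryo random 10 and 30, and with the residual component 24 and 48. The cause was not tested, except that independent cultures count 20 samples where there are 8 embryos. Leaving out each embryo gave 0 to 9 genes lower, 0 to 2 higher, 5 to 9 lists higher and 2 to 5 lower; the most genes, 2 higher and 9 lower, came without wild type embryo 2, the 2 lists lower without wild type embryo 1.

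Lists higher were 4 with quantile normalization, 4 without the 2 arrays and 4 with the embryo number as a block, which gave 2 lower; 0 higher and 0 lower passed with an estimated correlation or by permutation, and 0 higher and 1 lower with fry. With an embryo left out the G2/M list mean ran from -0.039 to 0.30 and the G1/S list mean from -0.14 to 0.24, both negative only without wild type embryo 2. Genes that differed between wild type embryos numbered 5683 with every probe set, 2172 with cultures 1 and 2 only and 1119 to 3390 with an embryo left out; between null embryos 983 to 1716 did. The labels do not say whether the embryo numbers pair the samples, and the values do not settle it. Same-numbered embryos deviated with r = 0.065, 0.634 and 0.447 across genes, and 0.634 was the highest of all pairs. Wild type embryos 1 and 3 correlated best with null embryos 4 and 5 (0.133 and 0.630). Nol11 was lowest in embryo 3 of both genotypes and Cap1 in embryo 2 of both. The same culture number gave a median r of -0.022 over 59 pairs. Signal over background is not known for these arrays, so low genes were only filtered.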

Other observations

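The tests of the counts against other splits were chosen after the counts were seen, except those of the random block and of the wild type cultures.

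With the embryo as a random block over the 20 cultures, 80 genes passed, a setting that called too many unchanged genes in simulated data. Among them 7 cholesterol synthesis genes were higher, all chosen here after their values were seen except Lss and Nsdhl: Lss (0.57, log2), Dhcr7 (0.52), Idi1 (0.50), Fdps (0.49), Nsdhl (0.46), Mvd (0.45) and Msmo1 (0.38). Of the amino acid stress list, 3 were higher: Psat1 and Shmt2, of serine and glycine metabolism, and Atf4, a transcription factor of the amino acid response, by 0.31 to 0.32. Lower were Nfkbia, Ccl7, Zfp36, Junb, Btg2 and Timp1, and Id1, an inhibitor of differentiation, at -0.77. Shmt2, Atf4, Junb and Id1 were also chosen after their values were seen.

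Other splits of the 8 embryos into 3 and 5 do not exclude chance for the counts between genotypes. At least 1 gene was called in 6 of 56 splits, up to 988 in another, 646 genes or more had an unadjusted p under 0.05 in 9 of 56, up to 2306, and 11 or more lists were called in 7 of 56, up to 14. With the random block 8 of 56 splits gave 80 genes or more, up to 1351, and with the residual component 11 of 56 gave 72 or more, up to 1499. The highest counts of genes came from the split that sets wild type embryo 2 and null embryos 1 and 2 against the rest, which points to a structure of the samples other than genotype. For wild type embryos, only the real grouping of the 10 cultures, 1 of 100 drawn, gave 3722 genes, the highest other giving 2364. This argues against chance there, but 100 draws do not exclude it.

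Culture 1 of wild type embryo 2 had an 18S control of 4572 and culture 2 of null embryo 4 a bioB spike-in of 1046.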
